A study of Mus musculus with 6 samples.

How the data were processed

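Gene expression was measured by RNA-seq in 6 libraries of TNFα-treated B16F10 mouse melanoma cells under amino acid limitation, 3 WT and 3 ZBTB5-S127A. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, reverse transcribed with random hexamers, amplified by PCR and sequenced by BGI as circularised single-stranded libraries. The selection of RNA and the strand setting are not given in the sources used here.

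The authors deposited 1 table of TPM per gene, a transcript abundance that divides reads by gene length and by the total of the library, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier, the annotation and the way in which the genes came to stand under upper-case, human-style symbols are not given in the sources used here. Of 14915 symbols, 14018 matched a mouse symbol of the GENCODE annotation of mm10 once that was written in upper case and 897 did not. At a mean TPM of at least 1, 24 sets of symbols (55 symbols) shared identical values in all 6 libraries, so 31 symbols repeated another. The columns summed to 863992 ± 903 TPM in WT and 831872 ± 1326 TPM in S127A (SD, n = 3), so 13.6% and 16.8% of the full TPM total lay in genes outside the table, and 530 symbols were at 0 in all 6 libraries. WT libraries had 9917 and S127A libraries 9681 genes at 1 TPM or more on average. TPM keeps no depth, so the depth of each library is unknown, no counting error could be given, and the spread between replicates is the error used.

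Genes with a mean TPM of at least 1 over the 6 libraries were tested on log2(TPM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend). The test was two-sided, with genotype as the only term, and adjusted by Benjamini-Hochberg over 10348 genes at a threshold of 0.05. A change of at least 2-fold was one with an absolute log2 fold change of 1 or more. Gene lists with at least 5 tested members were compared with the other genes by camera from limma with a preset correlation of 0.01, adjusted over the 24 lists tested. Camera with an estimated correlation, camera on ranks and fry were run beside it. ZBTB5 was also compared by an exact permutation test of its 6 values. Adjusted p-values are from limma throughout. Figures, splits by chromosome and summaries were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Coordinates come from the GENCODE annotation of mm10.

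The gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named the 10 largest rises and the 10 largest falls among genes that passed, had a mean of at least 5 TPM in a group and showed no overlap between the groups. It also named a panel of 10 genes whatever their values and, for each list, up to 4 members with the smallest adjusted p. The 28 lists covered TNF and NF-kB targets, TNF receptor signalling, mTORC1 components, ATF4 and amino acid response targets, amino acid transporters, aminoacyl-tRNA synthetases, lysosomal and autophagy genes, interferon-stimulated genes, MHC class I presentation, p53 targets, cell cycle, melanocyte genes, glycolysis and hypoxia, cholesterol synthesis, fatty acid synthesis, respiratory chain, mitochondrially encoded, ribosomal protein, unfolded protein response, extracellular matrix, cell death, heat shock, immediate early and histone genes, and markers of immune cells, of fibroblasts and of endothelial or epithelial cells.

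The alternatives were a pseudocount of 0.1 or 5, no filter or a mean TPM of at least 5, TMM factors computed on the TPM values, quantile normalization, limma with no trend or with robust hyperparameters, sample weights, a replicate block, and leaving out each library in turn. Counting identical symbols once and rescaling TPM to a common total within the table were added after seeing the data. A count model was not run, since the table holds TPM and no counts. The fit was tested on simulated data for 9733 genes, with their real WT means and the spread pooled within the WT and S127A groups. Of these genes 100 were changed by 0.5 and 100 by 1 on the log2 scale. Genes with a WT mean under 1 on the log2(TPM + 1) scale were left out. For S127A against WT the fit recovered 89% and 100.0% of the changed genes, and 5 of 194 calls were unchanged genes. In the real data 90.02% of tested genes changed, many of the largest rises from near 0 in WT, so these rates do not carry over to them. Some genes that the rule names are not reported here. Reads, isoforms and the sequence of ZBTB5 were not analysed here.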

Results

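The series profiled gene expression by RNA-seq in B16F10, a mouse melanoma cell line. Wild-type (WT) cells were set against cells of the same stated line in which ZBTB5, a zinc finger and BTB domain transcription factor, carried the S127A substitution, which replaces a serine that can be phosphorylated with alanine. All cells received TNFα, an inflammatory cytokine, under limited amino acids. The question, per the series' design text, was how blocking this phosphorylation affects transcription where inflammation activates mTORC1, the kinase complex that couples amino acid supply to growth. There were 3 WT and 3 S127A libraries and no untreated libraries were analysed here, so each difference is one between libraries labelled WT and S127A under treatment and not a response to TNFα. The values are TPM, transcript abundances normalised for gene length and library total, for 14915 gene symbols, given as mean ± SD with n = 3 per group unless stated otherwise. Fold changes are log2 differences of TPM + 1, S127A minus WT, which understate the change of low genes. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

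The edited gene itself was read in each library. ZBTB5 (ENSMUSG00000049657.9, chromosome 4, 44991242 to 45012412, minus strand, mm10) stood at 15.5 ± 0.54 TPM in WT and 8.90 ± 0.569 TPM in S127A. It fell by 0.74 on the log2 scale (SE 0.0618, adjusted p = 5.46e-07 by limma). The WT libraries held 15.9, 14.9 and 15.7 TPM and the S127A libraries 9.24, 8.24 and 9.21 TPM. A two-sided exact permutation test of the 6 TPM values gave p = 0.1, the smallest value that 3 against 3 allows. TPM per gene does not show the substitution, and 90.02% of all tested genes changed, so the level does not check the genotype labels.

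The WT libraries expressed a melanocyte transcriptome that the libraries labelled S127A lacked almost completely. PMEL, the fibril protein of the melanosome, stood at 3103 ± 34.5 TPM in WT and 4.44 ± 0.29 TPM in S127A (log2 change −9.16, SE 0.0401, adjusted p = 4.97e-16). The S127A libraries also held high levels of genes that were near 0 in WT. LCN2, a secreted siderophore-binding protein, stood at 0.293 ± 0.155 TPM in WT and 1140 ± 57.3 TPM in S127A (log2 change 9.79, SE 0.0775, adjusted p = 1.13e-14). Of 10348 genes tested, 9315 changed (90.02%), 4161 higher and 5154 lower in S127A, and 1033 did not pass. At least 2-fold changes numbered 3662 (35.4% of those tested), 1604 higher and 2058 lower, and 903 genes changed at least 8-fold. The excess of lower genes shrank with rescaling and turned for the 2-fold changes with quantile normalization. The higher share of the 2-fold changes was 43.8% on TPM as deposited, 49.0% with TMM factors and 50.7% with quantile normalization, and that of all changed genes 44.7%, 49.1% and 49.8%. Libraries of one group correlated across tested genes at r = 0.998 in each of 6 pairs, and libraries of different groups at r from 0.676 to 0.679 over 9 pairs (genes are not independent replicates, and no test was made of these r).

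The 10 largest rises that met the rule for named genes were in LCN2, LY6E, S100A6, EMP1, ANXA3, PTGS2, CD34, FOSL1, MSLN and VCAM1. S100A6, a calcium-binding protein, rose from 3.31 ± 1.53 to 2235 ± 22.0 TPM. PTGS2, the inducible cyclooxygenase, rose from 0.187 ± 0.0681 to 439 ± 10.4 TPM. CD34, a surface glycoprotein of progenitor and endothelial cells, rose from 0.813 ± 0.381 to 635 ± 4.98 TPM, and mesothelin (MSLN) rose from 0.41 ± 0.365 to 386 ± 11.9 TPM. The adhesion molecule VCAM1 rose from 0.243 ± 0.242 to 338 ± 4.71 TPM. LY6E reached 1505 ± 49.8 TPM, EMP1 1063 ± 29.3 TPM, ANXA3 627 ± 9.13 TPM and FOSL1 397 ± 15.1 TPM in S127A, each from 1.35 TPM or less in WT. The 10 largest falls were in DCT, MLANA, PMEL, TYRP1, FABP5, PTGDS, CKB, RAB38, MCAM and SLC24A5. FABP5, a fatty acid-binding protein, fell from 652 ± 44.6 to 0.48 ± 0.156 TPM, and the prostaglandin D synthase PTGDS fell from 1548 ± 41.2 to 2.97 ± 0.734 TPM. The brain-type creatine kinase CKB fell from 442 ± 12.5 to 0.357 ± 0.341 TPM, and the melanoma adhesion molecule MCAM from 551 ± 3.0 to 0.797 ± 0.189 TPM.

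**Figure D1:**
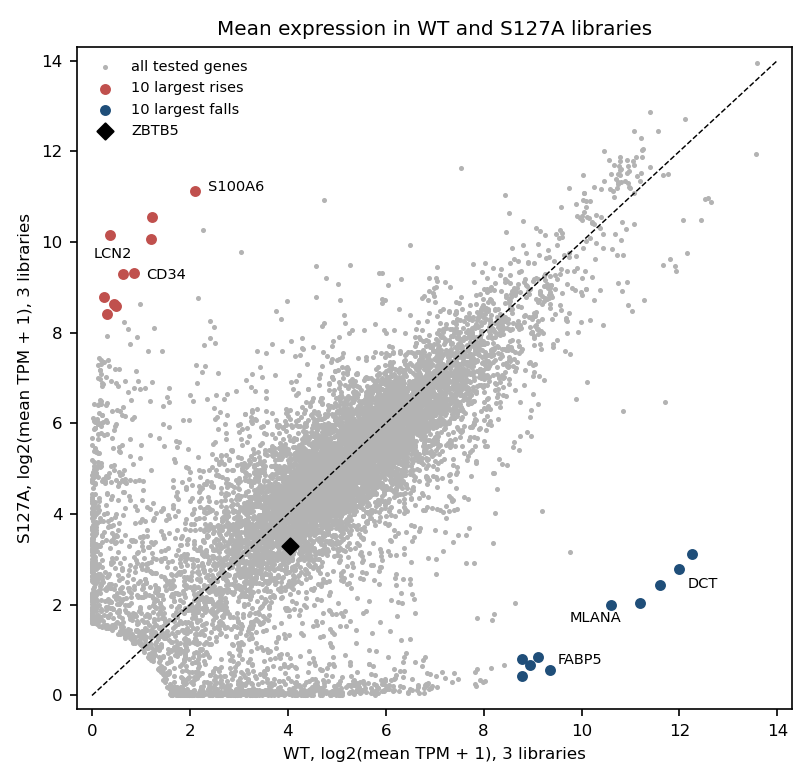
Mean expression of the tested genes in 3 WT libraries (x axis) and 3 S127A libraries (y axis), each as log2 of mean TPM + 1, with a dashed line of equal expression. Red and blue points are the 10 largest rises and the 10 largest falls, among them LCN2 at a log2 change of 9.79 and DCT at −9.23, and the black diamond is ZBTB5 at −0.74.

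Melanocyte and pigmentation genes fell as a group, with 22 of 22 tested members lower in S127A and a median log2 change of −6.03. The list stood apart from the other genes by camera (adjusted p = 1.18e-08, and adjusted p = 0.0556 with an estimated correlation). DCT, the dopachrome tautomerase of melanin synthesis, fell from 4094 ± 33.2 to 5.86 ± 0.658 TPM, and TYRP1, a further melanin synthesis enzyme, from 4886 ± 105 to 7.71 ± 1.42 TPM. The melanosome antigen MLANA fell from 2351 ± 44.3 to 3.09 ± 0.69 TPM, the melanosome trafficking GTPase RAB38 from 494 ± 11.4 to 0.59 ± 0.0866 TPM, and the melanosomal ion exchanger SLC24A5 from 440 ± 4.45 to 0.747 ± 0.358 TPM. GPNMB kept 88.0 ± 1.85 TPM of 3335 ± 83.1 TPM. MITF, the master transcription factor of the melanocyte lineage, fell from 143 ± 9.67 to 8.17 ± 0.487 TPM (log2 change −3.98). SOX10, a neural crest factor named after its values were seen, fell from 341 ± 4.64 to 0.603 ± 0.116 TPM.

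Markers of other cell types moved with the same libraries. Of 10 fibroblast markers 10 were listed and 5 reached the mean of 1 TPM needed for a test. Of these 4 rose and 1 fell, with a camera adjusted p of 0.0711 that did not pass. The collagen gene COL1A2 rose from 1.41 ± 0.164 to 275 ± 6.56 TPM, COL1A1 from 0.587 ± 0.0896 to 10.7 ± 0.447 TPM and the growth factor receptor PDGFRA from 0.383 ± 0.0252 to 5.98 ± 0.224 TPM, whereas POSTN fell from 7.79 ± 0.912 to 0.0667 ± 0.0231 TPM. The fourth that rose, PDGFRB, was named after its values were seen and rose by 0.69 on the log2 scale. Of 12 immune cell markers 8 were listed and 2 reached the mean of 1 TPM needed for a test, CD14, which was listed at 0 in the 3 WT libraries and stood at 45.1 ± 1.77 TPM in S127A, and CD68, which fell from 7.64 ± 0.601 to 4.69 ± 0.409 TPM. Of 10 endothelial or epithelial markers 9 were listed and 1 reached that mean. This was KRT18, a keratin of simple epithelia, which rose from 0.09 ± 0.09 to 62.8 ± 0.362 TPM. The other listed markers of the 3 lists lay below a mean of 1 TPM. Single markers such as COL1A2, CD14 and KRT18 therefore do not name a cell type.

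Targets of TNF and NF-kB signalling were mostly higher in S127A, with 23 of 28 tested members higher and 4 lower. The median log2 change was 1.23 (camera adjusted p = 1.04e-05, and adjusted p = 0.192 with an estimated correlation). TNFAIP3, a deubiquitinase that restrains NF-kB, rose from 5.54 ± 0.105 to 62.3 ± 1.96 TPM, and the NF-kB inhibitor NFKBIA from 66.2 ± 2.49 to 154 ± 10.7 TPM. The neutrophil chemokine CXCL2 rose from 22.9 ± 1.84 to 704 ± 7.52 TPM and the macrophage growth factor CSF1 from 89.6 ± 2.24 to 970 ± 14.1 TPM. The 4 members that fell, named after their values were seen, were CXCL10 (241 ± 18.3 to 58.3 ± 1.04 TPM), NFKBIE, TNIP1 and CCL5. CCL5 passed narrowly (log2 change −0.26, adjusted p = 0.0402) and did not pass with TMM factors (adjusted p = 0.173), which left 3 members lower. It also lost its call with quantile normalization (adjusted p = 0.126), with no trend (adjusted p = 0.0793) and without WT replicate 3 (adjusted p = 0.176), among others. The adjusted p of CCL5 ran from 0.000555 to 0.176 over 18 alternatives. MITF and SOX10 were low in the S127A libraries in which these genes were high.

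TNF receptor signalling components shifted upward, with 17 of 22 higher and 4 lower and a median log2 change of 0.49 (camera adjusted p = 0.0106, and adjusted p = 0.209 with an estimated correlation). The second TNF receptor, TNFRSF1B, rose from 0.2 ± 0.0794 to 25.4 ± 0.636 TPM, and RNF31, the catalytic subunit of the linear ubiquitin ligase, from 9.74 ± 0.867 to 33.8 ± 1.96 TPM. The death adaptor FADD fell from 25.8 ± 0.42 to 8.76 ± 0.499 TPM, CASP8 from 74.8 ± 1.58 to 42.7 ± 1.22 TPM and TAB2, named after its values were seen, by 0.68 on the log2 scale. TNFRSF1A, the main TNF receptor of most cells, stood at 101 ± 1.01 TPM in WT and 91.0 ± 2.16 TPM in S127A (log2 change −0.15, adjusted p = 0.00121). That call was lost with TMM factors (−0.05, adjusted p = 0.17) and with quantile normalization (−0.03, adjusted p = 0.327), and the adjusted p ran from 0.00104 to 0.327 over 18 alternatives.

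Components of the mTORC1 pathway were mostly lower in S127A, with 27 of 41 lower and 8 higher, and MTOR itself among the 6 that did not pass. The median log2 change was −0.61 (camera adjusted p = 0.0238, and adjusted p = 0.139 with an estimated correlation). MTOR stood at 25.7 ± 0.802 TPM in WT and 26.9 ± 0.425 TPM in S127A (log2 difference 0.06, SE 0.0443, adjusted p = 0.206). It passed with TMM factors (0.16, adjusted p = 0.00701), with quantile normalization (0.12, adjusted p = 0.0269) and with TPM rescaled to a common total (0.12, adjusted p = 0.0312), over a range of 0.00701 to 0.467 in 18 alternatives. The number of members higher was 12 with TMM factors, 13 with quantile normalization and 12 with a common total, with 27 lower in each. RPTOR, the subunit that recruits substrates, fell from 31.9 ± 0.58 to 22.98 ± 0.845 TPM, and RPS6KB1, the S6 kinase downstream of the complex, from 61.9 ± 2.62 to 30.9 ± 1.26 TPM. The Rag GTPase RRAGD fell from 21.4 ± 0.481 to 0.05 ± 0.05 TPM, SESN3 from 24.4 ± 0.71 to 0.02 ± 0.0346 TPM, the mTOR inhibitor DEPTOR from 29.8 ± 2.06 to 1.57 ± 0.111 TPM and AKT1 from 679 ± 13.7 to 203 ± 8.35 TPM. SESN3 and DEPTOR are known as inhibitors of the pathway, whereas RPTOR, RRAGD and AKT1 act in its activation. COL1A2 was at 275 TPM in the libraries where these levels were low.

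**Figure D2:**
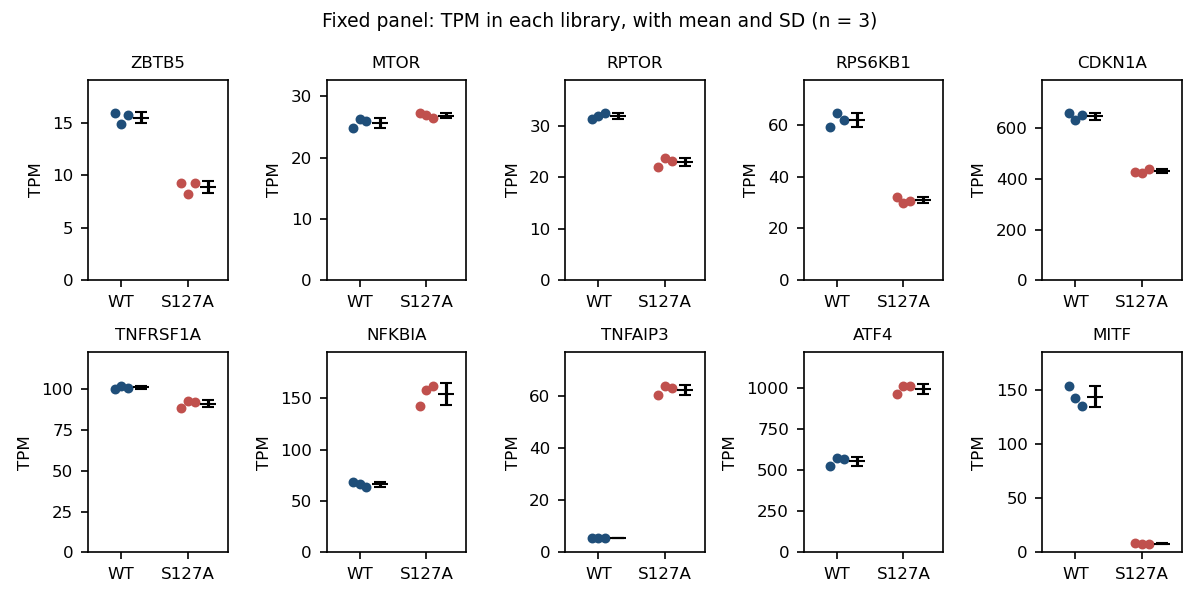
TPM of the 10 panel genes in each of 3 WT (blue) and 3 S127A (red) libraries, with black bars for mean ± SD and each y axis starting at 0. MTOR is the gene whose difference did not pass the test on TPM as deposited, and MITF falls from a mean of 143 to 8.17 TPM.

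Lysosomal genes were lower in S127A, with 29 of 36 lower and 5 higher and a median log2 change of −0.82 (camera adjusted p = 2.45e-04, and adjusted p = 0.0556 with an estimated correlation). Subunits of the proton pump fell, ATP6V1E1 from 604 ± 24.6 to 122 ± 0.873 TPM and ATP6V1D from 226 ± 8.03 to 44.1 ± 1.88 TPM. The protease CTSD fell from 1159 ± 26.7 to 310 ± 4.52 TPM and the hexosaminidase subunit HEXA from 305 ± 5.64 to 86.6 ± 1.47 TPM. The 5 that rose included MCOLN1 and CLN3, named after their values were seen. Autophagy genes went both ways, with 16 of 32 higher and 13 lower. Their list did not pass (camera adjusted p = 0.412) and its median log2 difference of 0.11 and mean of −0.17 differed in sign. OPTN, a receptor for selective autophagy, fell from 40.5 ± 1.85 to 0.17 ± 0.0265 TPM, UVRAG from 96.4 ± 3.62 to 17.3 ± 0.756 TPM and TMEM41B from 76.4 ± 2.57 to 26.9 ± 1.15 TPM, whereas ATG12 rose from 30.6 ± 1.76 to 94.0 ± 1.32 TPM. In these libraries the melanosome gene PMEL, whose product forms fibrils in a lysosome-related organelle, was at 4.44 TPM.

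Targets of ATF4 and the amino acid response were mostly higher in S127A, with 26 of 32 higher and 4 lower and a median log2 change of 0.80 (camera adjusted p = 2.72e-05, and adjusted p = 0.307 with an estimated correlation). ATF4, the transcription factor of the response, rose from 554 ± 26.6 to 993 ± 29.0 TPM. VLDLR rose from 0.0467 ± 0.0208 to 58.3 ± 1.35 TPM and PPP1R15A, a phosphatase subunit that acts on eIF2, from 25.8 ± 0.945 to 296 ± 6.01 TPM, while STC2 was listed at 0 in the 3 WT libraries and stood at 18.01 ± 0.633 TPM in S127A. Among targets named after their values were seen, the asparagine synthetase ASNS rose from 371 ± 17.0 to 744 ± 12.9 TPM, DDIT3 from 101 ± 6.18 to 237 ± 3.85 TPM and TRIB3 from 96.6 ± 9.5 to 217 ± 8.58 TPM. The 4 members that fell were ATF3 (40.9 ± 1.17 to 0.203 ± 0.0971 TPM), CTH, DDIT4 and MTHFD2, the last 3 of them named after their values were seen. The same S127A libraries held 0.603 TPM of SOX10.

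Amino acid transporters went both ways, with 9 of 23 higher and 10 lower, and the list did not pass (camera adjusted p = 0.823). The median log2 difference was −0.02 on TPM as deposited and 0.06 with TMM factors, and the mean was −0.23. The glutamine transporter SLC1A5 rose from 117 ± 4.77 to 484 ± 4.14 TPM and SLC38A4 from 0.01 ± 0.0173 to 29.6 ± 1.96 TPM. The taurine transporter SLC6A6 fell from 310 ± 6.42 to 22.3 ± 0.673 TPM and SLC38A1 from 208 ± 3.97 to 12.0 ± 0.415 TPM. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher for 12 of 18 and lower for 5, with a median log2 change of 0.22 (camera adjusted p = 0.048, and adjusted p = 0.513 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.0674), without WT replicate 2 (adjusted p = 0.0517) and with a replicate block (adjusted p = 0.0523). The adjusted p ran from 0.000283 to 0.513 over 21 alternatives. On rescaling, 2 members were lower with TMM factors, 2 with quantile normalization and 3 with a common total. LARS rose from 132 ± 4.39 to 331 ± 9.37 TPM, TARS from 155 ± 5.85 to 357 ± 5.16 TPM, NARS from 463 ± 16.9 to 865 ± 33.2 TPM and HARS from 118 ± 6.01 to 211 ± 4.12 TPM. Keratin KRT18 was at 62.8 TPM in the same S127A libraries.

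Interferon-stimulated genes were higher in S127A for 25 of 27 tested members, with a median log2 change of 2.61 (camera adjusted p = 1.39e-07, and adjusted p = 0.303 with an estimated correlation). IFI44 rose from 0.98 ± 0.0721 to 399 ± 20.4 TPM, the oligoadenylate synthetase OAS3 from 0.603 ± 0.0611 to 121 ± 2.19 TPM, the guanylate-binding protein GBP3 from 0.13 ± 0.131 to 158 ± 8.23 TPM and the nucleic acid sensor ZBP1 from 0.807 ± 0.155 to 69.9 ± 4.22 TPM. IFIT2 (58.3 ± 3.17 to 35.2 ± 2.26 TPM) and RSAD2 (36.4 ± 6.38 to 15.8 ± 1.41 TPM), named after their values were seen, fell. Genes of MHC class I antigen presentation rose for 11 of 12 tested members, with a median log2 change of 1.67 (camera adjusted p = 1.49e-04, and adjusted p = 0.139 with an estimated correlation). Of the 16 genes of this list 12 were listed, and those of the class I heavy chains were not found under their mouse symbols. The peptide transporter subunits TAP1 and TAP2 rose from 7.70 ± 0.333 to 72.8 ± 2.14 TPM and from 5.81 ± 0.561 to 98.7 ± 5.98 TPM. The immunoproteasome subunit PSMB8 rose from 0.163 ± 0.11 to 26.3 ± 1.2 TPM and PSME2 from 124 ± 2.85 to 466 ± 11.8 TPM. B2M, named after its values were seen, rose from 1046 ± 61.3 to 2852 ± 42.4 TPM, and PDIA3 was the 1 member that fell. CD14 was at 45.1 TPM and COL1A2 at 275 TPM in the same libraries.

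Genes of glycolysis and the hypoxia response were lower in S127A for 29 of 31 tested members, with a median log2 change of −1.82 (camera adjusted p = 3.41e-06, and adjusted p = 0.242 with an estimated correlation). The glycolytic enzymes PKM (3851 ± 83.1 to 705 ± 12.2 TPM), PGK1 (4573 ± 95.1 to 859 ± 14.5 TPM), ALDOA (3897 ± 64.7 to 653 ± 30.8 TPM) and PFKP (165 ± 4.44 to 9.39 ± 0.495 TPM) fell. GAPDH fell from 12151 ± 66.7 to 3958 ± 66.3 TPM and LDHA from 3235 ± 89.7 to 723 ± 14.7 TPM. GAPDH has many processed pseudogenes, so its level is uncertain where reads are shared. The 2 that rose were NDRG1 (36.8 ± 1.95 to 253 ± 4.28 TPM) and the angiogenic factor VEGFA (55.2 ± 3.79 to 113 ± 0.649 TPM). GAPDH, LDHA, NDRG1 and VEGFA were named after their values were seen. PMEL averaged 4.44 TPM and DCT 5.86 TPM in these S127A libraries.

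Cholesterol synthesis genes and SREBP2 targets were lower in S127A for 22 of 22 tested members, with a median log2 change of −2.87 (camera adjusted p = 1.59e-07, and adjusted p = 0.0556 with an estimated correlation). DHCR7, which acts late in sterol synthesis, fell from 300 ± 8.64 to 15.2 ± 0.116 TPM, HMGCS1 from 316 ± 0.8 to 36.1 ± 0.785 TPM and the sterol sensor partner INSIG1 from 357 ± 1.76 to 33.0 ± 0.402 TPM. Fatty acid synthesis genes were lower for 10 of 13 and higher for 2, with a median log2 change of −1.49 (camera adjusted p = 0.011, and adjusted p = 0.242 with an estimated correlation). FASN, the fatty acid synthase, fell from 497 ± 27.2 to 51.5 ± 1.5 TPM, FADS2 from 330 ± 11.1 to 33.5 ± 0.24 TPM, ACSL3 from 165 ± 4.92 to 18.8 ± 0.345 TPM and ACLY from 430 ± 6.78 to 87.2 ± 2.33 TPM. The 2 that rose, GPAM and AGPAT2, were named after their values were seen and act in glycerolipid assembly. SOX10, at 0.603 TPM, was low in the same libraries.

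Nuclear-encoded genes of the respiratory chain were lower in S127A for 54 of 60 tested members and higher for 4, with a median log2 change of −1.04 (camera adjusted p = 1.24e-07, and adjusted p = 0.0556 with an estimated correlation). SDHB, a subunit of succinate dehydrogenase, fell from 517 ± 7.18 to 130 ± 0.393 TPM, the ATP synthase subunit ATP5O from 834 ± 13.8 to 254 ± 7.47 TPM, and the cytochrome oxidase subunits COX7B and COX5A from 685 ± 14.9 to 216 ± 5.82 TPM and from 571 ± 5.68 to 216 ± 1.84 TPM. NDUFA2, NDUFA6, NDUFA7 and NDUFV1, named after their values were seen, rose. Ribosomal protein genes were higher for 63 of 68 and lower for 4, with a median log2 change of 0.61 (camera adjusted p = 1.86e-10, and adjusted p = 0.0556 with an estimated correlation), and 56 were higher and 5 lower after quantile normalization. RPLP0 rose from 2161 ± 29.5 to 5610 ± 225 TPM, RPL9 from 1511 ± 31.6 to 3610 ± 65.4 TPM, RPL37 from 446 ± 32.4 to 1406 ± 30.5 TPM and RPS20 from 179 ± 3.75 to 401 ± 8.17 TPM. RPS6, named after its values were seen, fell from 58.8 ± 8.16 to 24.7 ± 1.98 TPM. Ribosomal protein genes have many processed pseudogenes, so levels of single members are uncertain. Of the 13 mitochondrially encoded and 13 replication-dependent histone genes 0 were listed, so RNA selection could not be read from them. MITF was at 8.17 TPM in these S127A libraries.

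Cell cycle genes were mostly lower in S127A, with 31 of 42 lower and 10 higher and a median log2 change of −0.59 (camera adjusted p = 0.011, and adjusted p = 0.209 with an estimated correlation). The ribonucleotide reductase subunits RRM1 and RRM2 fell from 258 ± 2.96 to 103 ± 0.982 TPM and from 395 ± 7.24 to 169 ± 1.07 TPM, the mitotic kinase PLK1 from 128 ± 5.3 to 46.4 ± 0.682 TPM and cyclin gene CCNE1 from 68.6 ± 0.83 to 24.4 ± 0.768 TPM. The proliferation marker MKI67, named after its values were seen, fell from 171 ± 2.43 to 79.2 ± 2.83 TPM. Targets of p53 split, with 10 of 22 higher and 11 lower (camera adjusted p = 0.418), a median log2 difference of −0.05 and a mean of 0.68. With TMM factors the median was 0.04. CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, fell from 648 ± 13.9 to 431 ± 8.81 TPM (log2 change −0.59, adjusted p = 5.06e-09). PLK2 rose from 32.7 ± 0.71 to 418 ± 3.77 TPM, GADD45A from 54.3 ± 2.87 to 293 ± 7.51 TPM, EDA2R from 0.373 ± 0.0987 to 56.5 ± 1.19 TPM and the death receptor FAS from 0.11 ± 0.128 to 19.6 ± 0.204 TPM. KRT18 and COL1A2 were high in the same libraries, at 62.8 and 275 TPM.

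Cell death genes did not pass as a list (camera adjusted p = 0.135), with 11 of 20 higher and 7 lower and a median log2 difference of 0.53. The inflammatory caspase CASP1 rose from 0.133 ± 0.0924 to 60.9 ± 6.59 TPM, the pro-apoptotic BCL2L11 from 4.72 ± 0.41 to 47.2 ± 1.55 TPM and the anti-apoptotic BCL2L1 from 69.5 ± 2.58 to 162 ± 3.24 TPM. Genes of the unfolded protein response did not pass either (camera adjusted p = 0.412), with 6 of 21 higher and 12 lower and a median of −0.33. Of the 3 stress sensors 1 fell and 2 rose, EIF2AK3 falling from 66.1 ± 0.53 to 19.3 ± 0.346 TPM and ERN1 rising from 35.1 ± 0.394 to 114 ± 4.53 TPM, with ATF6, named after its values were seen, rising by 1.03 on the log2 scale. DNAJB9 rose from 39.8 ± 1.75 to 114 ± 3.34 TPM and SDF2L1 fell from 107 ± 5.09 to 20.5 ± 1.69 TPM. Heat shock genes did not pass (camera adjusted p = 0.554), with 3 of 10 higher and 6 lower and a median of −0.17. With TMM factors or a common total 4 were higher and 5 lower, and with quantile normalization 5 were higher and 5 lower. HSP90AA1 fell from 1832 ± 59.1 to 839 ± 29.6 TPM, DNAJA1 from 271 ± 5.82 to 147 ± 6.61 TPM and HSPD1 from 1643 ± 7.75 to 1148 ± 36.0 TPM, whereas HSPB8 rose from 28.5 ± 2.15 to 82.9 ± 1.4 TPM. CD14 was at 45.1 TPM in the same S127A libraries.

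Immediate early genes were mostly higher in S127A, with 15 of 20 higher and 4 lower and a median log2 change of 1.47 (camera adjusted p = 0.00101, and adjusted p = 0.0751 with an estimated correlation). EGR1 rose from 3.97 ± 0.0361 to 152 ± 2.16 TPM, the phosphatase DUSP5 from 0.243 ± 0.103 to 53.8 ± 1.2 TPM and the AP-1 subunit FOSL1 from 0.367 ± 0.112 to 397 ± 15.1 TPM. FOS, JUN and DUSP4, named after their values were seen, fell with ATF3. Genes of the extracellular matrix and the epithelial-mesenchymal transition (EMT) went both ways, with 17 of 26 higher and 9 lower and a median log2 change of 0.95 (camera adjusted p = 0.0213, and adjusted p = 0.307 with an estimated correlation). Fibronectin (FN1) rose from 31.7 ± 0.942 to 538 ± 13.6 TPM, osteopontin (SPP1) from 25.6 ± 3.26 to 1930 ± 43.3 TPM and the transcription factor TWIST1 from 0.1 ± 0.0436 to 73.9 ± 1.14 TPM, whereas SPARC fell from 1102 ± 12.3 to 119 ± 1.09 TPM. The fibroblast markers COL1A2 and POSTN moved in opposite directions in the same libraries.

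**Figure D3:**
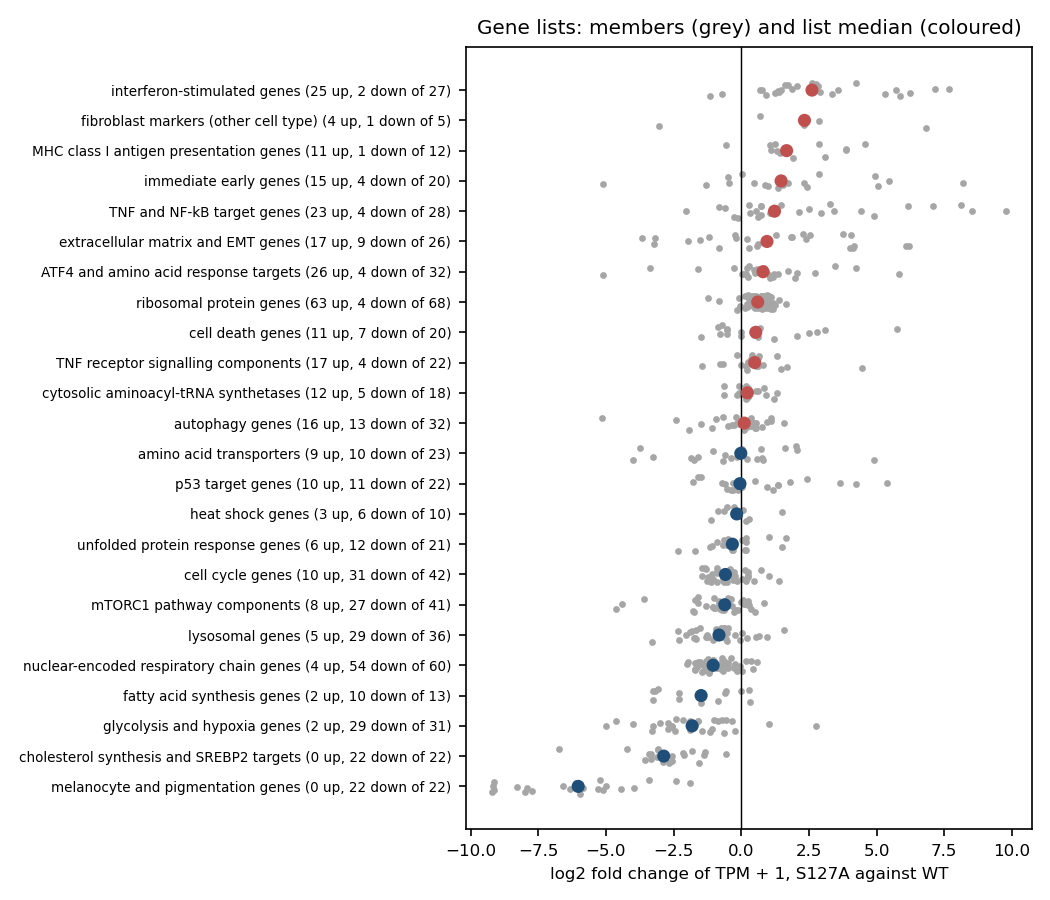
Log2 fold changes of TPM + 1, S127A against WT, of the members (grey) of the 24 lists tested, with the median of each list in red where above 0 and blue where below. The medians run from −6.03 for melanocyte and pigmentation genes to 2.61 for interferon-stimulated genes, and those of the amino acid transporters (−0.02) and p53 targets (−0.05) turn positive with TMM factors, quantile normalization or a common total.

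Of the 24 lists tested, 17 passed by camera with its preset correlation, 9 upward and 8 downward. By camera with an estimated correlation 0 passed (8 at an unadjusted p under 0.05), and by fry, which tests each list on its own, 24 passed. The numbers of members higher and lower adjusted over the list alone equalled those adjusted over the 10348 genes in each of the 24 lists. The median log2 difference of the tested genes was −0.12 on TPM as deposited, −0.02 with TMM factors and −0.0034 with quantile normalization, and a list median is to be read against that shift. The columns summed to 863992 ± 903 TPM in WT and 831872 ± 1326 TPM in S127A, and the genes that hold the rest of each library were not analysed here.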

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

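The alternatives that counted identical symbols once and that rescaled TPM to a common total were chosen after seeing the data. The number of genes changed ran from 8159 (mean TPM of at least 5) to 10593 (no filter) over the other settings and from 9123 to 9211 when 1 library was left out, against 9315. Genes changed at least 2-fold numbered 2640 with a pseudocount of 5 and 3930 with one of 0.1, and 3640 to 3670 when 1 library was left out, against 3662. The log2 change of ZBTB5 kept its sign and its call in 18 of 18 alternatives and ran from −0.76 to −0.69 when 1 library was left out. The 17 passing lists became 0 by camera with an estimated correlation, and the cause was not tested; they numbered 16 to 17 when 1 library was left out. By fry, amino acid transporters (adjusted p = 0.000118) and autophagy genes (adjusted p = 5.4e-05) passed downward against an upward direction by camera; the median and mean of autophagy genes differ in sign, and fry does not compare a list with other genes. Of the values of named genes under the alternatives, 3575 kept their sign and call, 13 no longer passed, in CCL5 and TNFRSF1A, and 3, all in MTOR, newly passed. With the replicate number as a replicate block 9339 genes changed, and the tRNA synthetases alone among the lists no longer passed (adjusted p = 0.0523). Deviations of libraries with the same number correlated at 0.117, 0.017 and 0.028, and those with different numbers at −0.076 to 0.054. No test was made of these values, and so few pairs cannot decide whether the numbers pair the samples. The fibroblast list had too few members for a test at a mean TPM of at least 5. Leaving out the S127A libraries that lack melanocyte genes would leave no comparison. DESeq2 was not run for want of counts, and depth could not be weighed, since TPM keeps none.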

Other observations

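The families in this part, the chromosome segments, and the tests of scaling, of a mixture and of carry-over were chosen only after the result was seen. Each family count covers the genes picked for it and not every member of the family, and 90.02% of all tested genes changed. S100 and annexin genes, which encode calcium-binding proteins, changed in both directions, with 13 of 18 tested members higher in S127A and 5 lower. S100A4 rose from 3.84 ± 1.45 to 1226 ± 25.5 TPM and ANXA2 from 352 ± 8.83 to 1196 ± 35.6 TPM (mean ± SD, n = 3), whereas S100B, which marks neural crest derivatives, fell from 46.1 ± 3.49 to 0.193 ± 0.112 TPM and ANXA6 from 54.5 ± 3.89 to 0.977 ± 0.133 TPM. Of 5 tested interleukin 1 receptor family genes 4 rose. IL1R1 went from 0.0267 ± 0.0252 to 32.6 ± 0.0693 TPM, IL1RL1 from 0.133 ± 0.0651 to 63.2 ± 1.95 TPM, IL1RL2 from 0.06 ± 0.03 to 40.1 ± 1.06 TPM and IL18RAP from 0.0267 ± 0.00577 to 57.9 ± 1.79 TPM, while the shared subunit IL1RAP fell from 20.8 ± 0.533 to 6.26 ± 0.556 TPM.

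HOX genes, which keep a record of the position of a cell along the body axis, also differed between the groups, with 5 of 11 higher, 4 lower and 2 not passing (6 higher with TMM factors or quantile normalization). HOXC6 rose from 0.15 ± 0.08 to 25.6 ± 0.634 TPM and HOXA9 from 1.19 ± 0.174 to 10.5 ± 0.45 TPM, whereas HOXD13 fell from 11.4 ± 0.948 to 0.0333 ± 0.0289 TPM and HOXB9 from 26.5 ± 0.542 to 4.63 ± 0.201 TPM. Of the 12 integrin genes picked 12 changed, 7 higher and 5 lower (4 lower with TMM factors), where 90.02% of all tested genes changed. ITGB7 rose from 0.4 ± 0.0854 to 117 ± 3.24 TPM and ITGB3 fell from 13.4 ± 1.26 to 0.143 ± 0.0902 TPM. Of 7 tested matrix metalloproteinases 4 were higher and 3 lower. MMP13, MMP10 and MMP3 were listed at 0 in the 3 WT libraries and stood at 28.2 ± 1.74, 12.0 ± 0.718 and 9.53 ± 0.668 TPM in S127A, and MMP14 fell from 159 ± 2.66 to 68.3 ± 0.4 TPM.

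The first pattern is the extent of the difference, 9315 genes changed and 3662 by at least 2-fold. Over the 10 splits of the 6 libraries, 1 split, the real one, reached each number, but 10 splits are too few for a share under 0.05. The highest of the other 9 called 0 genes by limma (at most 2 at an unadjusted p under 0.05). Each of those 9 mixed WT and S127A libraries within a group, which widens the spread, so their low numbers are built in and decide nothing. Scaling of the TPM values is argued against by the lowest number over 3 rescalings, 3646 genes changed at least 2-fold. Libraries labelled S127A from cells with other chromosome copy numbers, as another line or a diverged clone may have, remain a candidate explanation: the medians of 20 chromosomes over 7542 genes expressed in both groups had an SD of 0.276 on the log2 scale, against at most 0.0807 in 1000 shuffles (permutation p = 0.001, the smallest they can give), and ran from −0.47 to 0.29. An effect of the substitution, or of a lost melanocyte programme, that acts on each gene separately would give medians like those of the shuffles. For the 7542 genes the SD of 0.276 argues against such a gene-by-gene effect as the only cause. The shuffles treat neighbouring genes as independent, so changes that neighbours share could spread the medians without a copy number difference. No control for this was run. The substitution and a lost melanocyte programme therefore stay open and untested, as the whole or part of the difference. No copy number was measured here, and the 3 S127A libraries share whatever sets them apart from WT.

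Within chromosomes the median differed between segments whose breakpoints were picked by eye, which makes these values descriptive. On chromosome X the 54 genes from 1 to 40 Mb had a median log2 difference of −0.92 (95% bootstrap interval −1.23 to −0.77) and the 63 genes from 110 Mb on one of 0.73 (0.51 to 0.97). On chromosome 10 the 259 genes up to 90 Mb had a median of −0.43 (−0.54 to −0.34) and the 115 genes beyond it 0.36 (0.21 to 0.48). On chromosome 4 the 47 genes from 90 to 110 Mb had a median of −0.91 (−1.10 to −0.62) and the 271 genes from 110 Mb on 0.03 (−0.04 to 0.09).

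The second pattern is the near absence of melanocyte transcripts in the S127A libraries. A mixture that still holds 5% or more of cells like the WT cells is argued against by 8 genes at 500 TPM or more in WT that kept under 1% of that level in S127A, FABP5, MLANA, DCT, PMEL, MCAM, TYRP1, PTGDS and APOE, of 241 genes at that level. A loss of MITF and SOX10 expression in B16F10 cells and cells of another origin stay open, and no test here separates them.

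The last pattern is the low residue of these transcripts. The 8 genes kept a median of 0.144% of their WT level, with shares from 0.0736% in FABP5 to 0.917%, and 7 lay within 3-fold of that median. Of the 241 genes 0 lay more than 3-fold below it, but only these 8 could, since the others kept 1% or more. Carry-over of a small, fixed share of WT reads or RNA may give this, but 8 genes cannot tell it from low expression. In the other direction 8 of 210 genes at 500 TPM or more in S127A kept under 1% in WT, with a median of 0.126%, and 1 of them, LCN2 at 0.0257%, lay more than 3-fold below it, so carry-over of S127A reads or RNA cannot be told apart from low expression there, since 1 gene decides nothing. Low expression of these genes in each group stays open, and no biological explanation was tested.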
